A study of Sus scrofa with 11 samples.

How the data were processed

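RNA was measured by poly-A selected RNA sequencing in carotid artery of pigs (Sus scrofa) that received either carrier nanoparticles alone (SWNT) or the same carriers loaded with an inhibitor of the phosphatase SHP-1 (SWNT-SHP1i). Per the labels' protocols, RNA was extracted with Trizol, mRNA was captured on poly-T beads and cDNA was primed with random hexamers. The labels name no batch, sex, litter or sequencing date. Among the animals whose counts were analysed, numbers begin with B9 except in SWNT replicate 3 and SWNT-SHP1i replicate 3. The SWNT-SHP1i animal labelled as having died before harvest also lacks a B9 number. Nothing says that the range of animal numbers marks a batch.

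The values are whole read counts per gene, deposited by the authors as a single table with 35670 genes and without any normalization. Trim Galore, STAR and DESeq2 are named, with the build Sscrofa11.1, in the submitters' processing notes, which give no versions. The counting program, its strand setting and the annotation release are not given in the sources used here. Per the file headers, the table also holds each gene's coordinates, strand and summed exon length. Because the strand setting is unknown, reads of overlapping antisense genes cannot be assigned with certainty. Nor can reads of near-identical copies (for example in the globin and OAS families), whatever the strand setting. Read duplicates are not described, so the counts are reads, not independent molecules.

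The series lists 11 samples, 5 SWNT and 6 SWNT-SHP1i, each with its own animal number. For SWNT-SHP1i replicate 4, which is labelled as having died before harvest, no counts were analysed here. The comparison therefore rests on 10 libraries, 5 per group, named below by group and by replicate numbers given in accession order, which pair no animals. Library pairs were checked for double deposition. The lowest median chi-square per gene over all pairs was 5.4, where sampling noise alone gives 0.45, so all 10 were kept as separate replicates.

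Gene symbols came from the table itself for 16229 genes, from a table of gene identifiers and symbols for a further 229, and from RefSeq genes on Sscrofa11.1 at the same position for a further 869. A match by position needed an overlap of at least 0.5 of the union of both spans, best in both directions. Among 13991 named genes that also had such a match, 94.2% carried the same symbol. SIRPA is among the genes named by position.

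Counts were filtered with filterByExpr (minimum count 10), which left 15930 genes, and scaled by TMM. These genes hold at least 99.89% of the counts of every library. The main test was the quasi-likelihood test of edgeR 4.0.16 (robust fit, R 4.3.3) of SWNT-SHP1i against SWNT without covariates, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are log2 of SWNT-SHP1i over SWNT, with a standard error (SE). This SE is approximate, the absolute log2 fold change divided by the square root of the test's F statistic. The 95% intervals of fold changes use it. Levels of single genes are log2 CPM (counts scaled to a common library size) with a prior count of 2, as mean ± SD over 5 libraries. The fitted fold change compares mean counts and is pulled towards the highest libraries, so it can exceed the difference of the mean log2 CPM.

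There were 32 gene lists of pathways and cell types. The 31 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. The list of chemoreceptor, neuroendocrine, thyroid and parathyroid markers had 3 tested members and was not tested. Camera with a correlation estimated for each list, fry and camera on ranks were run beside it. A list score per animal is the mean of the centred log2 CPM of its members, and its group difference was tested by a two-sided exact permutation test over all 252 assignments of the 10 libraries, whose smallest possible p is 0.00794. Members are counted over all genes tested and, separately, adjusted over the list alone.

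The sample groups, the lists, the test and most alternatives were chosen before the data were examined. So was the rule for the genes named, which takes PTPN6, CD47 and SIRPA, the 12 higher and 12 lower genes with a symbol and the smallest p, and the members with the smallest p of each list described. Of the genes this rule takes, 1 of the 12 higher genes and 1 list member are not reported here. The alternatives were RLE and upper-quartile scaling, no filter and a stricter filter (1 CPM), a fit that is not robust, DESeq2 1.42.0, limma-voom with quality weights, the range of animal numbers as a term, 1 surrogate variable from sva 3.50.0 as a term, globin and mitochondrial genes left out, a threshold of 0.1, the median in place of the mean for list scores, and each library left out in turn. Added after seeing the data were fits without SWNT-SHP1i replicates 3 and 6, fits of the animals with B9 numbers alone, and an offset for each library's trend on gene length.

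The procedure was tested on simulated counts for 15414 genes drawn from the means and library sizes of this comparison, 5 against 5, with 50 genes changed at each of 4 sizes. The edgeR test recovered 18% of the genes changed 2-fold, 64% at 4-fold, 86% at 8-fold and 84% at 16-fold, with 3 unchanged genes called. With no gene changed it called 0 genes and camera called 0 lists, in simulated genes that vary independently of each other. Totals of 27593564 to 47718854 counts per library mean that the spread between animals, with a common biological coefficient of variation of 0.52, and not counting error, sets the precision for all but the lowest genes.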

Results

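Carotid artery was taken from pigs kept for 12 weeks on a high-fat, high-calorie diet. Each week the animals received an intravenous infusion at 400 nM of either single-walled carbon nanotubes alone (SWNT) or nanotubes carrying the SHP-1 inhibitor (SWNT-SHP1i). SHP-1, the product of PTPN6, is the phosphatase that carries the inhibitory signal of SIRPA, the macrophage receptor for CD47, which marks cells not to be engulfed. The study asked whether inhibiting SHP-1 in macrophages lowers the load of dying cells and inflammation in the diseased vessel without causing anaemia. The counts cover 5 SWNT and 5 SWNT-SHP1i animals. The total counts in SWNT replicates 1 to 5 were 42242812, 34424082, 47718854, 36116326 and 32931527, and in SWNT-SHP1i replicates 1, 2, 3, 5 and 6 they were 38508174, 39413481, 37652943, 32754092 and 27593564.

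Markers of macrophages, fibroblasts and the extracellular matrix and genes of complement were higher as lists in SWNT-SHP1i than in SWNT carotid artery, while genes of contractile smooth muscle and of Schwann cells and nerve were lower. These calls use a preset correlation between genes, and none held with a correlation estimated for each list (adjusted p of 0.231 to 0.255). SWNT-SHP1i replicates 3 and 6 stand apart from the other libraries. All 20 macrophage markers had positive fold changes, and their mean level was 2.09-fold higher. The macrophage list score was -0.53 ± 0.57 (SD, n = 5) in SWNT and 0.53 ± 1.06 in SWNT-SHP1i. HMOX1, the enzyme that degrades haem, had the smallest p of all single genes, but no single gene passed the test over all genes. Lists of inflammatory cytokines and of efferocytosis, the engulfment of dying cells, were not called in either direction.

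Of 31 lists, camera with a preset correlation called 15 higher and 3 lower at an adjusted p under 0.05. With a correlation estimated for each list it called 0, with a smallest adjusted p = 0.231. Fry called 0 lists (smallest adjusted p = 0.297), and the exact permutation test of the list scores also called 0 (smallest adjusted p = 0.287).

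The macrophage list differed by 1.07 on the log2 scale (adjusted p = 2.03e-12 with the preset correlation, adjusted p = 0.231 with an estimated correlation). The list had an estimated correlation of 0.626 between genes, where the preset was 0.01. It had an exact permutation p = 0.103 on its score. Its score lay above the highest SWNT library in 3 of 5 SWNT-SHP1i libraries. CD163, the scavenger receptor for haemoglobin, had a log2 fold change of 1.82 ± 0.45 (SE) and was the only member to pass adjusted over the list alone (adjusted p = 0.0315), while 0 members passed over all genes tested. The lipopolysaccharide co-receptor CD14 (1.71 ± 0.56) and the lysosomal glycoprotein CD68 (1.84 ± 0.63) came next, both with an adjusted p = 0.0506 over the list. Replicate 6, the SWNT-SHP1i library least like the rest, had the highest macrophage score (1.94). Without replicate 6 the fold changes of CD14 and CD68 were 0.88 and 1.11. Without replicates 3 and 6 the list difference was 0.73 (adjusted p = 9.39e-05 with the preset correlation).

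Genes of lipid-handling macrophages were higher by 0.91 (adjusted p = 6.65e-06, adjusted p = 0.255 with an estimated correlation). Of 19 tested members, 16 had positive fold changes and 8 passed adjusted over the list alone, against 0 over all genes. The passing members were led by ACP5, the tartrate-resistant acid phosphatase (5.74 ± 1.51), GPNMB (2.43 ± 0.68) and the lipid carrier APOE (2.33 ± 0.73), which were 2.92, 1.51 and 0.89 without replicate 6. SPP1, which encodes osteopontin, had a log2 fold change of 4.47 ± 1.55 that came from replicate 6, where it reached 1390 CPM against 6.83 to 21.1 CPM in the other 9 libraries. Without that library SPP1 gave -0.68. The list differed by 0.46 without replicate 6 and by 0.47 without replicates 3 and 6 (adjusted p = 0.0375).

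The LXR and cholesterol efflux genes were higher by 0.43 (adjusted p = 0.000347, adjusted p = 0.255 with an estimated correlation), with 12 of 13 members positive. ABCA1, the cholesterol exporter, had a log2 fold change of 0.80 ± 0.22, and it and APOE were the 2 members that passed adjusted over the list alone (0 over all genes). Without replicate 6 the list differed by 0.19, and without replicates 3 and 6 by 0.20, where it was no longer called (adjusted p = 0.131). Cholesterol synthesis genes were not called (0.07, adjusted p = 0.186, adjusted p = 0.669 with an estimated correlation), although they were called higher without SWNT-SHP1i replicate 1 (0.12) or 3 (0.20) and without replicates 3 and 6 (0.27, adjusted p = 0.0222).

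Genes of haem and iron handling were higher by 0.66 (adjusted p = 0.00942, adjusted p = 0.231 with an estimated correlation), and 4 of 15 members passed adjusted over the list alone against 0 over all genes. HMOX1 stood at 4.30 ± 0.88 log2 CPM in SWNT and 7.44 ± 2.63 in SWNT-SHP1i, with a log2 fold change of 4.59 ± 1.11, and was above every SWNT library in 4 of 5 SWNT-SHP1i libraries. The other passing members were CD163, the metal transporter SLC11A1 (4.10 ± 1.07) and the biliverdin reductase BLVRB (2.27 ± 0.70). Without replicate 6 HMOX1 gave 2.69, SLC11A1 2.41 and BLVRB 0.99. This call was lost without SWNT-SHP1i replicate 6 (0.42, adjusted p = 0.132) and without SWNT replicate 3 (0.45, adjusted p = 0.0649). It was also lost without replicates 3 and 6 (0.44, adjusted p = 0.36), over the animals with B9 numbers (0.51, adjusted p = 0.099) and on ranks (adjusted p = 0.0527). The erythroid and globin genes went the other way by -0.91 without being called (adjusted p = 0.068, adjusted p = 0.533 with an estimated correlation). ALAS2, the first enzyme of haem synthesis in red cells, had a log2 fold change of -1.46 ± 0.81, and AHSP, a chaperone of alpha globin, of -2.14 ± 1.12. This list was called lower without SWNT replicate 2 (-1.18) or 5 (-1.30) and without SWNT-SHP1i replicate 1 (-1.16) or 3 (-0.93). Without SWNT replicate 3 the list differed by -0.41 (adjusted p = 0.565) and ALAS2 by -0.28. The list difference was -0.49 without replicates 3 and 6 and -0.51 over the animals with B9 numbers.

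Neutrophil markers were higher by 1.49 (adjusted p = 0.000175, adjusted p = 0.26 with an estimated correlation), and 4 of 8 tested members passed adjusted over the list alone against 0 over all genes. PGLYRP1 had a log2 fold change of 3.53 ± 1.01, the gelatinase MMP9 of 5.54 ± 1.79 and the receptor CSF3R of 2.29 ± 0.77. MMP9 was at 193 CPM in replicate 6 and at 0.0581 to 6.16 CPM elsewhere, and without that library MMP9 gave 1.23, CSF3R 1.51 and the list 0.86. With a surrogate variable as a term the list differed by 0.82. Without replicates 3 and 6 it differed by 0.23 and was not called (adjusted p = 0.638), with PGLYRP1 at 2.12.

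Complement genes were higher by 0.61 (adjusted p = 1.37e-07, adjusted p = 0.231 with an estimated correlation), with C7 (1.31 ± 0.42), C1R (0.71 ± 0.23) and C4A (1.38 ± 0.45) first, and 13 of 17 members positive. Interferon-stimulated genes were higher by 0.29 (adjusted p = 4.08e-05, adjusted p = 0.29 with an estimated correlation). OAS1, a sensor of double-stranded RNA, had a log2 fold change of 0.97 ± 0.24, IFIT3 of 1.04 ± 0.33 and OAS2 of 0.78 ± 0.26. The interferon score was above the highest SWNT library in 3 SWNT-SHP1i libraries and below the lowest in the other 2, and the list differed by 0.16 without SWNT-SHP1i replicate 3. MHC class II and antigen presentation genes were higher by 0.32 (adjusted p = 0.00556, adjusted p = 0.551 with an estimated correlation), with CD86 at 0.72 ± 0.27 and CTSS at 1.21 ± 0.47. That call ended without SWNT replicate 2 (0.14), without SWNT-SHP1i replicate 6 (0.07) and without replicates 3 and 6 (-0.03), while the difference was 0.54 without SWNT-SHP1i replicate 5. The interferon call ended over the animals with B9 numbers (0.14, adjusted p = 0.099), and with a surrogate variable as a term both the interferon call (0.16, adjusted p = 0.0503) and the MHC class II call (0.21, adjusted p = 0.135) ended. CTSS gave 0.67 without SWNT-SHP1i replicate 6, and C7 gave 0.80 without SWNT-SHP1i replicate 2. In these 3 lists 0 members passed over all genes or adjusted over the list alone.

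Inflammatory cytokines, chemokines and adhesion molecules differed by -0.05 and were not called (adjusted p = 0.709, adjusted p = 0.917 with an estimated correlation). Their scores were 0.03 ± 0.60 (n = 5) in SWNT and -0.03 ± 0.61 in SWNT-SHP1i. The chemokine CXCL2 had a log2 fold change of -3.77 ± 1.27, which came from SWNT replicate 3 with 384 CPM against 2.44 to 12.7 CPM in the other 9 and was -0.16 without that library, and IL18 one of 1.46 ± 0.52. Of 31 members 0 passed, either over all genes or adjusted over the list alone.

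Efferocytosis receptors, bridging molecules and engulfment genes differed by 0.17 and were not called (adjusted p = 0.0869, adjusted p = 0.255 with an estimated correlation), with 15 of 26 members positive. The scavenger receptor STAB1 had a log2 fold change of 1.05 ± 0.38 and the transglutaminase TGM2 one of -0.83 ± 0.34. The list was called higher without SWNT replicate 1 (0.26, adjusted p = 0.0261) and without SWNT-SHP1i replicate 5 (0.24, adjusted p = 0.0409). Apoptosis and cell death genes differed by -0.02 (adjusted p = 0.503, adjusted p = 0.615 with an estimated correlation), with RIPK3 at 0.56 ± 0.28 (0.28 without SWNT-SHP1i replicate 6) and MLKL at 0.45 ± 0.26. The apoptosis difference ran from -0.154 to -0.021 with 1 library left out. In both lists 0 members passed over all genes or adjusted over the list alone.

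Contractile smooth muscle genes were lower by -0.69 (adjusted p = 1.72e-08, adjusted p = 0.255 with an estimated correlation), with 18 of 20 members negative and 0 past the threshold over all genes or adjusted over the list alone. CNN1, the smooth muscle calponin, stood at 12.13 ± 0.25 log2 CPM in SWNT and 11.26 ± 0.44 in SWNT-SHP1i (log2 fold change -0.84 ± 0.24) and was lower in every SWNT-SHP1i library than in any SWNT library. The actin-binding proteins TAGLN (-0.67 ± 0.21) and TPM2 (-0.57 ± 0.20) came next. Replicate 6 had the lowest score of the list (-1.75). The difference was -0.34 without that library and -0.20 without replicates 3 and 6, and the list was still called in both fits with the preset correlation.

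Schwann cell and nerve markers were lower by -0.65 (adjusted p = 0.00119, adjusted p = 0.231 with an estimated correlation), with their score below the lowest SWNT library in 4 of 5 SWNT-SHP1i libraries. SOX10, the transcription factor of the Schwann cell lineage, had a log2 fold change of -0.83 ± 0.29 and the neuregulin receptor ERBB3 of -1.07 ± 0.45. The Schwann list differed by -0.41 without replicate 6 and by -0.30 without replicates 3 and 6, still called with the preset correlation (adjusted p = 0.0014 in the latter). Immediate early and heat shock genes were lower by -0.51 (adjusted p = 0.0307, adjusted p = 0.62 with an estimated correlation), with ATF3 at -2.40 ± 1.02 and ZFP36 at -1.42 ± 0.66, although ATF3 gave -0.75 without SWNT replicate 4 and ZFP36 -0.03 without SWNT replicate 3. SWNT replicate 3 had the highest score of that list (1.69), and the call ended without that library (-0.15), without SWNT replicate 4 (-0.43) and without SWNT-SHP1i replicate 1 (-0.34) or 2 (-0.47). It also ended without replicates 3 and 6 (-0.43, adjusted p = 0.0633) and over the animals with B9 numbers (-0.05, adjusted p = 0.959). The list differed by -0.76 without SWNT replicate 5 and by -0.78 without SWNT-SHP1i replicate 5. In these 2 lists 0 members passed over all genes or adjusted over the list alone.

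Extracellular matrix genes were higher by 0.39 (adjusted p = 5.88e-06, adjusted p = 0.231 with an estimated correlation), and 21 of 25 members were positive. The proteoglycan VCAN had a log2 fold change of 1.64 ± 0.47, the collagen COL1A1 of 0.98 ± 0.29 and CTHRC1 of 2.0 ± 0.63, with 0 members past the threshold over all genes or adjusted over the list alone. Fibroblast markers were higher by 0.62 (adjusted p = 1.17e-05, adjusted p = 0.231 with an estimated correlation), and the Wnt-binding proteins SFRP2 (4.88 ± 1.31) and SFRP4 (1.21 ± 0.34) passed adjusted over the list alone, against 0 over all genes. Without replicate 6 SFRP2 gave 1.97 and CTHRC1 1.03. Cell cycle genes were higher by 0.31 (adjusted p = 1.59e-05, adjusted p = 0.267 with an estimated correlation), with positive fold changes in 24 of 24 members, among them MKI67 at 0.76 ± 0.39 and MCM4 at 0.61 ± 0.32. This difference was 0.17 without SWNT-SHP1i replicate 6, 0.20 without SWNT or SWNT-SHP1i replicate 2 and 0.48 without SWNT-SHP1i replicate 3, and it was 0.51 with a surrogate variable as a term and 0.47 over the animals with B9 numbers. MCM4 gave 0.27 without SWNT-SHP1i replicate 6. Endothelial markers were higher by 0.27 (adjusted p = 0.0427, adjusted p = 0.645 with an estimated correlation), with ESAM at -0.54 ± 0.23 and ENG at 1.0 ± 0.48, and this call was lost without SWNT replicate 2 (0.12), 4 (0.22) or 5 (0.08) and without SWNT-SHP1i replicate 2 (0.18), 5 (0.30) or 6 (0.11), while the difference was 0.56 without SWNT replicate 3 and 0.68 over the animals with B9 numbers. The endothelial call was also lost with RLE scaling (adjusted p = 0.0546), no filter (adjusted p = 0.0599) or the stricter filter (adjusted p = 0.0516) and without replicates 3 and 6 (0.22, adjusted p = 0.287). ENG gave 0.28 without SWNT-SHP1i replicate 6. Acute phase and oxidative stress genes were higher by 0.47 (adjusted p = 0.00113, adjusted p = 0.231 with an estimated correlation), with GCLM at 0.96 ± 0.28 and GCLC, the other subunit of the enzyme that starts glutathione synthesis, at 0.82 ± 0.36. They differed by 0.24 without SWNT replicate 2 and by 0.23 with no low-count filter. They were not called without replicates 3 and 6 (0.15, adjusted p = 0.267) or over the animals with B9 numbers (0.29, adjusted p = 0.0921). In the last 3 lists 0 members passed over all genes or adjusted over the list alone.

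Mitochondrially encoded genes were higher by 0.90 (adjusted p = 7.63e-07, adjusted p = 0.26 with an estimated correlation), with ND6 at 1.43 ± 0.53 and ND2 at 1.31 ± 0.53 and 0 members past the threshold over all genes or adjusted over the list alone. Their share of all counts was 8.61% in SWNT-SHP1i replicate 3 and 1.16% to 2.97% in the other 9 libraries, and the list differed by 0.45 without that library and by 0.38 without replicates 3 and 6 (adjusted p = 0.0462). With a surrogate variable as a term it differed by 0.32 (adjusted p = 0.0404). ND6 gave 0.63 and ND2 0.59 without replicate 3. Nuclear genes of oxidative phosphorylation differed by 0.09 and were not called (adjusted p = 0.109, adjusted p = 0.692 with an estimated correlation), but they were called higher without SWNT replicate 4 (0.12) and without SWNT-SHP1i replicate 1 (0.13) or 5 (0.18), and called lower without replicates 3 and 6 (-0.14, adjusted p = 0.0014).

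Markers of other cells of the vessel wall and its surroundings were not called with all 10 libraries. T and NK lymphocyte markers differed by -0.28 (adjusted p = 0.663), B cell and plasma cell markers by 0.18 (adjusted p = 0.0869), adipocyte markers by -0.11 (adjusted p = 0.965), epithelial and glandular markers by -0.40 (adjusted p = 0.558), osteochondrogenic genes by -0.36 (adjusted p = 0.198) and hypoxia genes by -0.09 (adjusted p = 0.593). With 1 library left out, B cell markers were called higher without SWNT replicate 1 (0.42) or 5 (0.34) and without SWNT-SHP1i replicate 5 (0.40), and T and NK markers were called lower without SWNT replicate 2 (-0.57) and without replicates 3 and 6 (adjusted p = 0.0462). B cell markers differed by 0.01 without SWNT replicate 2 and 0.05 without SWNT-SHP1i replicate 6, epithelial markers by -0.13 without SWNT replicate 3, and osteochondrogenic genes by -0.12 without SWNT-SHP1i replicate 3. Skeletal muscle markers differed by 0.14 (adjusted p = 0.965), but 2 of 7 members passed adjusted over the list alone (0 over all genes) in opposite directions, the muscle creatine kinase CKM at 2.61 ± 0.69 and the slow troponin TNNC1 at -0.56 ± 0.18. For 4 lists (apoptosis, inflammatory, adipocyte and skeletal muscle) the direction given by camera differed from the sign of the mean difference, and for skeletal muscle the median also differed in sign from the mean.

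**Figure D1:**
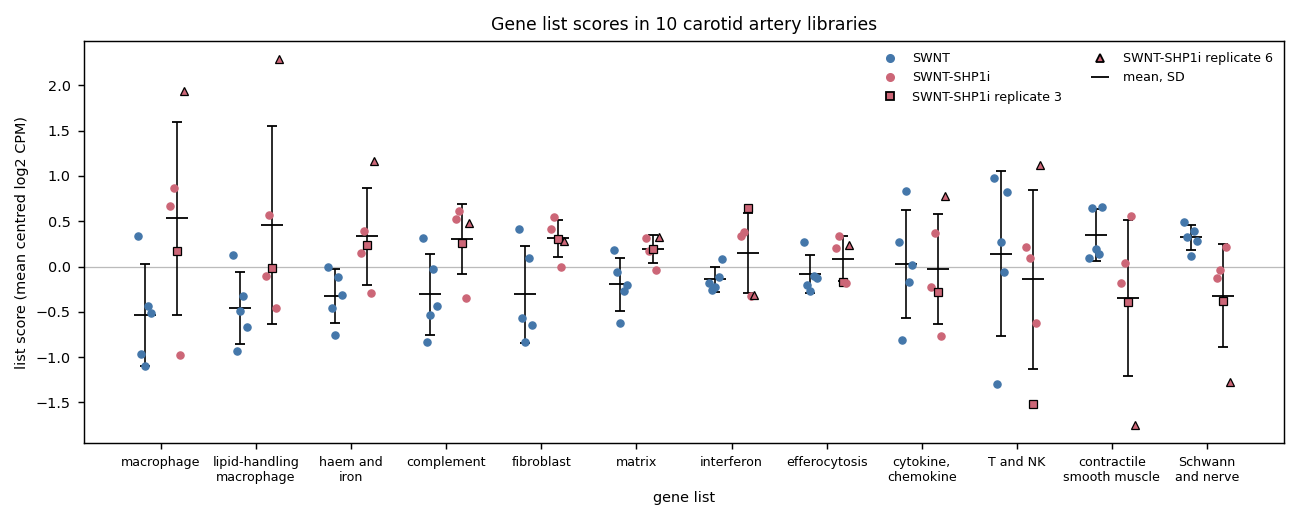
Scores of 12 gene lists (vertical axis, mean of the centred log2 CPM of the members) in each of 5 SWNT and 5 SWNT-SHP1i libraries, with mean and SD as bars; squares and triangles mark SWNT-SHP1i replicates 3 and 6. The macrophage score runs from -1.10 to 0.34 in SWNT and from -0.98 to 1.94 in SWNT-SHP1i, and the contractile score reaches -1.75 in replicate 6.

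No gene passed an adjusted p under 0.05 in the edgeR quasi-likelihood test over 15930 genes, where the smallest adjusted p was 0.997. At an unadjusted p under 0.05 there were 739 genes, 556 higher and 183 lower in SWNT-SHP1i. With no effect and uniform p-values 796 would be expected. Other splits of the same libraries gave a median of 470, so 796 need not be the count without an effect here. DESeq2 called 1 gene and limma-voom 0. The groups did not overlap for 57 genes, 13 higher and 44 lower, a share of 0.36% where chance gives 0.79%. The unadjusted 95% interval of a log2 fold change reached 0.73 to either side for the median gene. A call after adjustment over all genes needs a larger change than that. In simulated counts 18% of genes changed 2-fold and 64% of those changed 4-fold were recovered. Those counts vary independently between genes and hold no library that stands apart, so the rates need not hold for these data. HMOX1, with a fitted change of 24.2-fold, did not pass here, so the absence of calls does not exclude large changes.

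The higher genes with the smallest p are given as values that did not pass, with an adjusted p = 0.997 each. Beside HMOX1, CD163, OAS1, SLC11A1, ACP5 and CKM they were the short-chain fatty acid receptor FFAR2 (3.03 ± 0.74), C1QTNF3 (1.22 ± 0.31), the cation channel TRPV4 (2.50 ± 0.63), the aminopeptidase ANPEP (1.80 ± 0.46) and the coagulation factor chain F13A1 (1.93 ± 0.51). TRPV4 and ANPEP were higher in every SWNT-SHP1i library than in any SWNT library, with 1.41 and 1.14 without replicates 3 and 6. ACP5 was at 10.72 log2 CPM in replicate 6 and at -0.37 in replicate 5, and its fold change was 3.0 without replicates 3 and 6, where HMOX1 gave 2.86 and CD163 1.51.

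The 12 lower genes with the smallest p also did not pass. Beside CNN1 they included the LIM protein CSRP1 (-0.80 ± 0.25), the small heat shock protein HSPB7 (-1.02 ± 0.29), the adrenergic receptor ADRA1D (-1.09 ± 0.32) and RAMP1 (-0.84 ± 0.26), a subunit of the receptor for the neuropeptide CGRP. GFAP, the intermediate filament of glia, was at 4.78 ± 0.30 log2 CPM in SWNT and 3.54 ± 0.65 in SWNT-SHP1i (-1.15 ± 0.30). PRKAG3 (-1.19 ± 0.31), a subunit of AMP-activated kinase, the brain-type creatine kinase CKB (-0.69 ± 0.19), FAM131A (-0.94 ± 0.26), KLHL30 (-1.41 ± 0.40), RRAD (-1.0 ± 0.29) and COCH (-0.98 ± 0.29) completed the set. For all of these except RRAD and CSRP1, every SWNT-SHP1i library lay below every SWNT library.

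The genes of the inhibited pathway were measured as RNA, which an enzyme inhibitor need not alter. As a list, CD47-SIRPA-SHP-1 signalling genes were higher by 0.50 (adjusted p = 4.08e-05, adjusted p = 0.255 with an estimated correlation), with 12 of 14 members positive. The difference was 0.31 without replicate 6 and 0.26 without replicates 3 and 6 (adjusted p = 0.0295). Among its leading members were the Fc receptor chain FCER1G (1.43 ± 0.52) and the kinase PTK2B (1.08 ± 0.39), which were 0.79 and 0.67 without replicate 6, and 0 members passed over all genes or adjusted over the list alone. PTPN6 (chromosome 5, 63762112 to 63808350) was at 4.16 ± 0.45 log2 CPM (n = 5) in SWNT and 5.13 ± 1.21 in SWNT-SHP1i, a log2 fold change of 1.34 ± 0.51 with an exact permutation p = 0.135 (adjusted p = 0.202 over the 3 pathway genes). SIRPA (chromosome 17, 33566271 to 33611603) gave 5.43 ± 0.39 and 6.26 ± 0.78, a log2 fold change of 0.98 ± 0.37 with an exact permutation p = 0.0397 (adjusted p = 0.119). CD47 (chromosome 13, 151429288 to 151488544) gave 7.36 ± 0.14 and 7.31 ± 0.57, a log2 fold change of 0.01 ± 0.24 (95% interval -0.51 to 0.54). Without replicate 6 the fold changes of PTPN6 and SIRPA were 0.58 and 0.47. Of the other genes that lead the lists, CD163 lies on chromosome 5 at 63300231 to 63334498, CNN1 on chromosome 2 at 70183364 to 70190752 and HMOX1 on an unplaced scaffold, all as spans of whole annotated genes on Sscrofa11.1 with reads summed over exons.

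**Figure D2:**
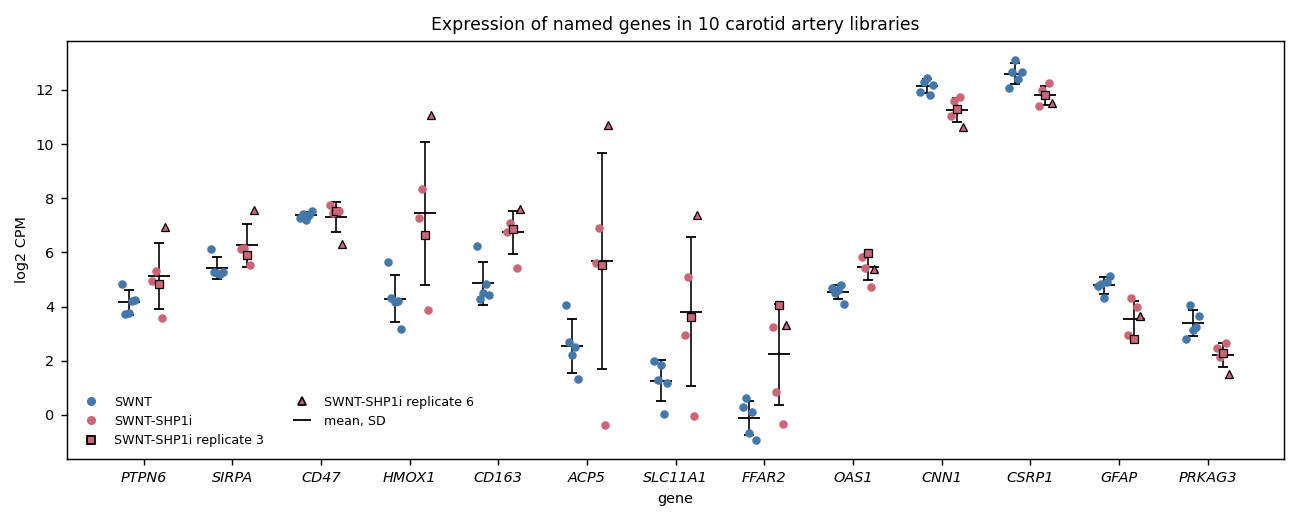
Expression (vertical axis, log2 CPM) of 13 named genes in each of 5 SWNT and 5 SWNT-SHP1i libraries, with mean and SD as bars; squares and triangles mark SWNT-SHP1i replicates 3 and 6. HMOX1 reaches 11.09 in replicate 6, and every SWNT-SHP1i library lies below every SWNT library for CNN1, GFAP and PRKAG3.

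The libraries did not resemble each other equally. Pearson correlations between pairs, across genes, ran from 0.802 to 0.979. The median correlation of a library with the other 9 was 0.839 for SWNT-SHP1i replicate 6 and 0.871 for replicate 3, against 0.924 to 0.963 for the rest. In replicate 3, 59.4% of all genes had no count, against 44.1% to 51.6% elsewhere. In replicate 6 the trend per doubling of gene length was -0.263 on the log2 scale, where the other libraries lay between -0.041 and 0.14. The first principal component, with 37.4% of the variance, put replicates 3 and 6 apart from the other libraries. The second, with 29.2%, put them at opposite ends, replicate 3 at -97 and replicate 6 at 152.3, with the other libraries between -26.6 and 14.4. The third, with 12.1%, put SWNT replicate 3 apart.

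**Figure D3:**
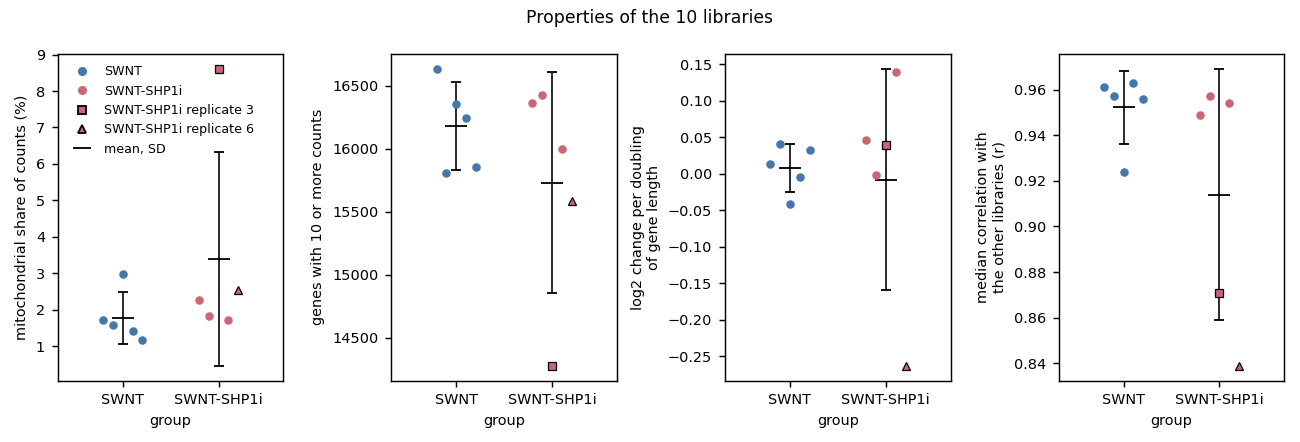
Mitochondrial share of the counts (%), genes with 10 or more counts, log2 change per doubling of gene length and median Pearson correlation with the other libraries, for each of 5 SWNT and 5 SWNT-SHP1i libraries, with mean and SD as bars. SWNT-SHP1i replicate 3 (square) has 8.61% mitochondrial counts and replicate 6 (triangle) the lowest median correlation, 0.839.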

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

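The tests of the macrophage difference against replicate 6, gene length and the share of smooth muscle were chosen after that difference was seen, and the tests on replicates 3 and 6 were fixed before their results. Each value below is the highest or lowest of the 5 libraries of its group by more than Dixon's 95% limit allows. Over 126 such checks 10 values passed the limit, where chance gives about 6.3.

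SWNT-SHP1i replicate 3 had 8.61% of its counts on mitochondrially encoded genes, against 1.71% to 2.55% in the other 4 libraries of its group, and a score of 2.25 for that list, against at most 0.28. FAM131A was at 3.13 log2 CPM there and at 3.98 or more in the others. In replicate 6 the score of the LXR and cholesterol efflux genes was 1.17, against at most 0.05, and CD47 was at 6.31 log2 CPM, against at least 7.44. SWNT replicate 1 had higher levels of the macrophage genes SIRPA (6.13 log2 CPM, others at most 5.29) and CD163 (6.24, others at most 4.82) and a lower level of RRAD (5.33, others at least 6.55). SWNT replicate 3 had a hypoxia score of 0.24, against at most 0.04, and RAMP1 at 7.65 log2 CPM, against at most 6.69.

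SWNT-SHP1i replicate 3 stood apart from the other libraries, with a median correlation of 0.871. Leaving out the mitochondrial genes moved this hardly at all (0.87), as it did the lowest value among the 8 libraries that do not stand apart (0.923), so that test decides nothing and the part of its high share of mitochondrial RNA stays open. Sparse sampling of genes with low expression remains a candidate explanation. Over the genes with a mean above the median its median correlation was 0.898, inside the range of those 8 libraries, whose lowest was 0.891. That lowest value was 0.924 over all genes, so the test passed by a small margin against a lower limit. Replicate 6 was at 0.714 over the same genes. The total of replicate 3, 37652943 counts, lay within the range of the other libraries, so a low depth is not what sets it apart. SWNT replicate 3, the other analysed animal without a B9 number, had the next highest mitochondrial share (2.97%). It also had the next highest share of genes with no count (51.6%). Whether the range of animal numbers has a part in this was not tested. No biological explanation was tested for SWNT-SHP1i replicate 3, a single animal.

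SWNT-SHP1i replicate 6 had the lowest median correlation, 0.839, and the steepest trend on gene length. With the length trend taken out the median correlation was 0.849, still below the lowest value of 0.925 among the 8 libraries, which argues against length bias as the whole cause. The library also combined the highest macrophage score (1.94) with the lowest contractile score (-1.75). Which part of the vessel wall was sampled, or how advanced the disease was in this animal, was not tested.

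The macrophage list was higher in SWNT-SHP1i by 1.07, and 3 explanations were set against a response to the inhibitor, the difference the design names. A trend on gene length is argued against, because the difference was still 1.07 (SE 0.53) with the trend taken out, as before, and the list was still called with the preset correlation. A smaller share of smooth muscle alone would raise the markers of every other cell type alike. The macrophage score moved apart from the T and NK score by 1.35 (exact permutation p = 0.0159, n = 5 per group, and 1.09 without replicate 3, exact permutation p = 0.0397). It did not move clearly apart from the endothelial score (0.8, exact permutation p = 0.214). Fibroblast (0.62) and matrix (0.39) lists were also higher and the contractile list lower (-0.69), as a smaller share would give, while the Schwann list was lower (-0.65). The lists thus point both ways, and a smaller share of smooth muscle stays open. Whether replicate 6 carries the whole difference stays open, since without it the difference was 0.71 with an SE of 0.49. Of the 20 macrophage markers 2 also stand in another list, and a larger share of macrophages in the pieces sampled and a response to the inhibitor both may give this pattern and stay open, untested.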

How the results depend on the processing

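The fits without SWNT-SHP1i replicates 3 and 6, of the animals with B9 numbers and with a gene length offset were chosen after seeing the data. The planned fit with the animal that died before harvest could not be run, because the counts used here hold none for that animal. No paired analysis was possible because the replicate numbers follow accession order and the animals are separate.

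The count of genes past an adjusted p under 0.05 was 0 under every alternative run for single genes except DESeq2, which called 1 gene (NUGGC, lower, chosen after its value was seen, adjusted p = 0.035) while 509 genes had no adjusted p. The smallest adjusted p otherwise lay between 0.0933 (limma-voom) and 1. At an unadjusted p under 0.05 the main 739 genes became 1583 without SWNT-SHP1i replicate 5, 421 without SWNT replicate 2, 436 without SWNT replicate 5, 1668 with no filter, 1171 with DESeq2, 1400 with limma-voom and 296 with a surrogate variable. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry 0 and 0, in place of 15 and 3. Without SWNT replicate 2 the lists called lower became 5, and with 1 library left out they ran from 2 to 5 and those called higher from 12 to 17. The 15 lists called higher became 10 without replicates 3 and 6, with 4 lower. Among lists not called with all libraries, erythroid genes were called lower with the range of animal numbers (adjusted p = 0.0428), a surrogate variable (0.00672), ranks (0.0442) or the length offset (0.0329). B cell markers were called higher with the stricter filter (0.0265), cholesterol synthesis genes with a surrogate variable (0.00789) and nuclear oxidative phosphorylation genes on ranks (0.0442). With the median in place of the mean, tested by permutation, no list was called (smallest adjusted p = 0.197). Limma-voom, which weights the libraries, gave smaller fold changes for HMOX1 (2.97), ACP5 (2.74), SLC11A1 (2.38), SFRP2 (2.58), FFAR2 (1.70), CKM (1.57) and ATF3 (-0.31). Among the 18 called lists 10 stayed called in every alternative that kept the preset correlation, the fit on ranks included. All of these share the preset, so they do not test it. The macrophage difference ran from 0.72 to 1.44 over them. PTPN6 kept a positive fold change of 0.58 to 1.58 and SIRPA one of 0.47 to 1.20.

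CD47, near 0 throughout, ran from -0.095 to 0.192 with 1 library left out and was -0.062 over the B9 animals. Except for MHC class II, the lists that turned in direction were not called with all libraries. Nuclear oxidative phosphorylation genes were the only list called in the opposite direction, lower by -0.136 without replicates 3 and 6 (adjusted p = 0.0014). With 1 library left out, adipocyte markers ran from -0.473 to 0.156, inflammatory genes from -0.264 to 0.147, T and NK markers from -0.572 to 0.064, cholesterol synthesis genes from -0.043 to 0.2, nuclear oxidative phosphorylation genes from -0.064 to 0.179 and skeletal muscle markers from -0.052 to 0.381. With a surrogate variable as a term, adipocyte markers turned to 0.22, T and NK markers to 0.098, apoptosis genes to 0.038 and nuclear oxidative phosphorylation genes to -0.004. With a stricter filter adipocyte markers turned to 0.054 and apoptosis genes to 0.056, which were 0.008 with RLE scaling. With the median in place of the mean adipocyte markers gave 0.106 and inflammatory genes 0.053. Without replicates 3 and 6, adipocyte markers gave 0.022, B cell markers -0.047, MHC class II genes -0.029 and MMP9 -0.026. Over the B9 animals adipocyte markers gave 0.362, inflammatory genes 0.21, T and NK markers 0.097, epithelial markers 0.049 and ZFP36 0.032. ALAS2 gave 0.094 with limma-voom. SPP1 ran from -0.675 (without SWNT-SHP1i replicate 6) to 4.786 with 1 library left out and gave -0.771 without replicates 3 and 6 and -0.41 with limma-voom. Apart from the libraries left out, the cause was not tested. Depth limits these calls less than the spread between animals does.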

Other observations

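The tests in this part on the term for the macrophage score and on the animals with B9 numbers were chosen after the results were seen, while the split counts and the relation of PTPN6 with the macrophage score were set out before. SWNT replicate 3 carried a set of stress and cytokine transcripts that were lower in the other libraries. FOS was at 532 CPM there, against 9.92 to 225 elsewhere, the nuclear receptor NR4A1 at 1330, against 20.2 to 220, the interleukin IL6 at 16.4, against 0 to 1.81, and the cyclooxygenase PTGS2 at 137, against 1.16 to 10.5. These genes were chosen after their values were seen. It also had the highest erythroid score, 2.46.

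SWNT-SHP1i replicate 6 held SPP1, MMP9 and the lipid receptor TREM2 at levels seen in no other library, with TREM2 at 51.4 CPM there, against 0 to 11.6 in the other 9. These genes were chosen after their values were seen. CKM was at 146, 162 and 79.1 CPM in SWNT-SHP1i replicates 1, 3 and 6, against 7.22 to 23.6 in the other 7 libraries. The Y-linked gene KDM5D was at 0 CPM in SWNT replicate 4 and 0.415 in SWNT-SHP1i replicate 1, at 1.06 and 13.4 in SWNT-SHP1i replicates 3 and 6, and at 19.3 to 23.8 in the other 6. EIF1AY, also Y-linked, gave 0 and 0.104, then 5.79 and 8.23, then 19.4 to 30 in the same libraries. The near absence of both genes in SWNT replicate 4 and SWNT-SHP1i replicate 1 would be seen if the sexes were mixed in both groups. Sex is not in the labels and no fit took it into account, so its part in the group differences was not tested.

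Chance cannot be excluded for the list calls. Among 100 of the 126 splits of the 10 libraries into groups of 5, the real split called 18 lists, the highest other split 22, and 10 of the 100 called at least 18. For single genes the real split called 0 and the highest other split 1. With a count of 0 every one of the 100 splits calls at least as many, so that count decides nothing about chance. At an unadjusted p under 0.05 the real split gave 739 genes, the other splits a median of 470, and 26 of the 100 splits gave at least 739. The highest, 2189, came from the split that exchanges SWNT replicate 3 with SWNT-SHP1i replicate 5, so that structure among the libraries other than the treatment may add to these counts.

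A hypothesis tested here is that PTPN6 RNA in these samples follows how much macrophage RNA each holds. Over 10 libraries PTPN6 correlated with the macrophage score with Pearson's r = 0.98 (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 5e-05 over 5 relations) and Spearman's rho = 0.94 (permutation p = 0.00029, adjusted p = 0.00145). With the group means taken out r was 0.97, without the 2 libraries farthest from the median it was 0.97 (permutation p = 0.00105), and over the 8 animals with B9 numbers it was 0.98 (exact permutation p = 7.44e-05). The 2 animals with other numbers are too few for a value. The correlation is what the hypothesis calls for, but SIRPA (r = 0.93) and HMOX1 (r = 0.94) followed the score nearly as closely. With the macrophage score as a term the difference of PTPN6 between the groups was -0.14 ± 0.18 (SE), where it was 0.97 log2 CPM without it. A term that correlates with PTPN6 at 0.98 takes up most of its difference whatever the cause. Macrophage content was not measured apart from this RNA score, so the fit cannot tell content from a change of PTPN6 shared with the marker genes.

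The other 4 relations with the macrophage score were those of SIRPA (r = 0.93, permutation p = 0.00031, adjusted p = 0.000517, rho = 0.82, permutation p = 0.00568), HMOX1 (r = 0.94, permutation p = 0.00017, adjusted p = 0.000425, rho = 0.88, permutation p = 0.00158), the contractile list (r = -0.85, permutation p = 0.00222, adjusted p = 0.00277, rho = -0.79, permutation p = 0.00893) and CD47 (r = -0.54, permutation p = 0.103, rho = -0.08, permutation p = 0.838). Without the 2 farthest libraries r was 0.87, 0.84, -0.73 and 0.43, so that the negative value of CD47 rests on those libraries. The contractile relation no longer passed there (permutation p = 0.0454, adjusted p = 0.0567), while those of SIRPA and HMOX1 did (adjusted p = 0.0205 each). Over the 8 animals with B9 numbers r was 0.93, 0.95, -0.90 and -0.66. With the macrophage score as a term, for CD163 computed without CD163 itself, the difference of CD163 was 1.03 ± 0.30 (SE). Those of HMOX1, CNN1 and SIRPA were 0.89 ± 0.63, -0.51 ± 0.18 and 0.13 ± 0.23. The permutation test did not test these fitted differences. It compared the groups on the residuals of a fit on the score alone, and is approximate because the score differs between the groups. For CD163 it gave a permutation p = 0.0397 (adjusted p = 0.159 over 5 genes). HMOX1 had a permutation p = 0.262, CNN1 a permutation p = 0.0635 and SIRPA a permutation p = 0.627.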
